A study of Mus musculus with 7 samples.

How the data were processed

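Arrays of 7 samples were analysed: stage 1 NKT of Valpha14 transgenic mice (2), of Luxoid Valpha14 transgenic mice (3) and wild-type CD4SP thymocytes (2). Per the labels' protocols, RNA was extracted from sorted cells, amplified and converted to biotin-labelled cDNA, and hybridised to single-colour Affymetrix mouse arrays. Per the submitters' processing notes, the values were made with RMA and Affymetrix Expression Console; versions and the probe annotation build are not given in the sources used here. RMA corrects background, normalizes between arrays by quantiles and summarises probes into probe sets, which fixes the distribution of values per array and compresses small differences between dim probe sets. The deposited values are intensities on a linear scale from 3.08 to 20875, although log2 values had been assumed in the fixed design; log2 was therefore taken first, as the design provided for. No 2 arrays held identical columns, and the array medians were 79.6 to 83.7.

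Genes were named from the GEO platform annotation. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were not listed, and none was named from a probe set with several. Of the probe sets with 1 symbol 34741 matched the RefSeq table of GRCm38.p6 by gene ID, which changed 0 symbols. That table was also used to tell which genes lie on X or Y and which lie near Zbtb16, and none of its coordinates is given. For each of 18193 genes the probe set with the highest mean was kept, and genes were tested if it reached an intensity of 82.0, the 50th percentile of all values, in 2 or more arrays, which left 10874 genes. Detection calls were not used here, and the same intensity served as the floor for folds of named genes: where every array of the dimmer group lay under it, the brighter group was divided by 82.0, and no fold is given where the brighter group also lay under it. These bounds were added after the data were seen. Of the called genes with further probe sets, some had a probe set of opposite sign: 3 of 77, 71 of 796 and 108 of 934 for Luxoid against stage 1 NKT, stage 1 NKT against CD4SP and Luxoid against CD4SP.

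A linear model with a mean per group was fitted to the log2 values of all 7 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 3 groups shared 1 estimate of the spread with 4 residual and 4.49 prior degrees of freedom. Each contrast was adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 is called past the threshold. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg over 25 lists per contrast, and again with an estimated correlation and with fry. With the estimated correlation no list was called in any of the 3 contrasts, and 3, 3 and 5 lists had an unadjusted p under 0.05 in the order given above; a reported list direction therefore rests on the preset value. Counts of members are given over all genes tested and adjusted over the list alone.

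The 26 lists were fixed before the data were examined. They were 15 programmes (Th1 and NK effector, type 2, type 17, cytokine receptors, homing and adhesion, naive T cell and recirculation, transcription factors, cell cycle, T cell receptor signalling and activation, SLAM and SAP, ribosome biogenesis, glycolysis, cholesterol synthesis, survival and apoptosis, interferon-stimulated) and 11 sets of markers (B cell, myeloid or dendritic, immature double-positive thymocyte, CD8 lineage, regulatory T, NK cell, gamma delta T, erythroid, thymic epithelium, handling stress, sex of the mice). Some genes stand in more than 1 list, and T cells express many of the marker genes. Named genes followed a rule also fixed then: all probe sets of Zbtb16, the 12 largest changes in each direction among called genes whose groups do not overlap, up to 4 called members per list, and a set of T cell genes that may be named whatever their test.

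On simulated data with the means and spread of the real genes and 200 of 10874 genes changed, the fit recovered 7.46%, 80.6% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale for Luxoid against stage 1 NKT, with 5 false calls. For stage 1 NKT against CD4SP these were 5.97%, 82.1% and 100% with 5 false calls, and for Luxoid against CD4SP 5.97%, 83.6% and 100% with 10. A list of 20 genes shifted by 0.5 was called in each contrast. Of the 25 other lists only those sharing no gene with it were counted, and 0 of these were called. In 100 further simulated sets without any shift, camera at the preset correlation called at least 1 of the 25 lists in 12, 19 and 16 sets for the 3 contrasts, more than the 5% that the adjustment allows. The cause was not tested, and genes were simulated without correlation, so a list called at the preset value may be a false call more often than its adjusted p says. The chance that groups do not overlap is 20% for 2 against 3 arrays and 33.3% for 2 against 2, and no contrast has 3 arrays in both groups, so other splits of the samples were not counted.

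The labels number the replicates. Deviations from the group means correlated between same-numbered arrays of different groups at r = 0.334 to 0.491 in 6 pairs, and at r = 0.261 to 0.442 without genes of X and Y. Deviations of the 2 arrays in a group of 2 mirror each other, so the 6 pairs are not 6 separate observations. Same-numbered arrays may thus be paired, which the labels do not state. The main fit, which gave the reported differences, SE, adjusted p and counts, has no such pairing. A fit with the replicate number as a block was made beside it, and its values are marked as such. Luxoid array 3 is the only array numbered 3, so the block absorbs it. Block differences therefore equal those without Luxoid array 3 (2.13 for Gcsam between the NKT groups in both), and the 2 settings are not separate checks of a difference. The alternatives tried were other intensity filters, a trended and robust eBayes, array weights, another quantile normalization, median centring, other rules for a gene's probe set, fits of only the compared groups, the block, a 2-fold threshold, and leaving out each array in turn. Where an array of a group of 2 was left out, the lone array was assumed to vary like the other groups. If that group lay outside the contrast, leaving out either of its arrays gave the fit of only the compared groups. Those settings are therefore not separate checks. A covariate for Y-linked expression and the removal of the mixed-sex pools were added after the data were seen.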

Results

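Gene expression was measured in T cells sorted from the thymus of mice on a C57BL/6J background, aged 4 to 6 weeks, with 7 single-colour Affymetrix mouse arrays. Natural killer T (NKT) cells are T cells that recognise lipids presented by CD1d, and stage 1 is an early step of their maturation. It was sorted here by binding of a CD1d tetramer, low CD24 and absence of CD44 and NK1.1. The arrays fell into 3 groups: stage 1 NKT of Valpha14 T cell receptor transgenic mice (n = 2), stage 1 NKT of mice that carried the same transgene and the Luxoid mutation (n = 3), and conventional CD4 single-positive (CD4SP) thymocytes of wild-type mice (n = 2). Luxoid is a mutation of Zbtb16, the gene of the transcription factor PLZF, and the mutant mice are described as lacking PLZF. For the CD4SP samples 1 label repeats the stage 1 NKT sort, while their titles, sources and descriptions name CD4SP thymocytes. The latter were followed. Each sample came from pooled mice, and the labels call the samples biological replicates.

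The deposited values were intensities with medians of 79.6 to 83.7 per array, and 10874 genes were tested. Over all probe sets, arrays of 1 group correlated at r = 0.984 to 0.992, and arrays of either NKT group with those of CD4SP at r = 0.968 to 0.979. Arrays of the 2 NKT groups correlated with each other at r = 0.981 to 0.992, so they were about as alike as arrays of 1 group. The number of arrays limited the precision. Differences are given on the log2 scale as the difference ± SE with the adjusted p of limma, and intensities are geometric means of the 2 or 3 arrays. Where every array of the dimmer group read under the intensity filter, the fold is a lower bound against the filter value and is written as at least N-fold. Xist and the Y-linked genes showed that the pools differed in sex within every group: Y-linked Kdm5d was at 6.49 to 11.7 in the arrays numbered 1 and at 758 to 2331 in the others. Xist was at 36.1 and 29.0 in Luxoid array 2 and CD4SP array 2 and at 3888 or more in the others. Stage 1 NKT array 2 and Luxoid array 3 carried both signals.

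Zbtb16 itself was examined first. Its brightest probe set read 2751 and 3488 in the stage 1 NKT arrays, 1857, 2774 and 2645 in the Luxoid arrays, and 87.3 and 61.8 in the CD4SP arrays. By this probe set the transcript was 42.2-fold higher in stage 1 NKT than in CD4SP (log2 difference 5.40 ± 0.25, adjusted p = 1.04e-05) and 32.5-fold higher in Luxoid NKT than in CD4SP (5.02 ± 0.23, adjusted p = 5.13e-06). By the 2 dimmer probe sets it was at least 17.2-fold and 8.98-fold higher in stage 1 NKT and at least 9.41-fold and 5.32-fold higher in Luxoid NKT. Luxoid minus stage 1 NKT was -0.38 ± 0.23 for the brightest probe set (adjusted p = 0.607), -0.87 ± 0.20 for a probe set at 1263 and 1580 in stage 1 NKT (adjusted p = 0.0931), and -0.76 ± 0.14 for one at 728 and 745 (adjusted p = 0.0360). The array measures the transcript, so these values do not check the loss of the protein, nor do they check the labels of the 2 NKT groups. By every probe set the CD4SP arrays read far below all NKT arrays. This argues against the CD4SP label that repeats the stage 1 NKT sort.

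The comparison of Luxoid with unmutated stage 1 NKT addressed which transcripts depend on PLZF at this stage. The largest rise was that of Kcnj8, a subunit of ATP-sensitive potassium channels, which went from 111 to 1529 (3.78 ± 0.20, adjusted p = 0.000107). Fgl2, a secreted fibrinogen-like protein, went from 86.5 to 1130 (3.71 ± 0.23). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose 7.11-fold (2.83 ± 0.20, and 1.38 with the mean of its probe sets), and Snx9, a sorting nexin, rose at least 3.89-fold (1.83 on the log2 scale with the mean of its probe sets). Il10ra, a chain of the interleukin 10 receptor, rose 5.73-fold (2.52 ± 0.18, and 1.64 with the mean of its probe sets), and its gene lies within 10 Mb of Zbtb16 in the GRCm38.p6 assembly. Lratd1 rose at least 3.97-fold and Cd200r1 at least 3.93-fold. Sema4f (5.55-fold), Ramp3 (5.53-fold) and Chl1 (4.61-fold, and 1.57 on the log2 scale with the mean of its probe sets) rose as well. Nrp2 rose 4.65-fold, with another probe set of that gene pointing the other way.

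The largest fall was that of Gm36723, a predicted gene, from 1609 to 42.8 (at least 19.6-fold, adjusted p = 0.000107). Ctla2a, related to the propeptide of cathepsin L, was 8.25-fold lower (-3.04 ± 0.16), and Lgals3, which encodes galectin 3, was 5.71-fold lower (-2.51 ± 0.16). St6galnac3 (5.52-fold, and -1.31 on the log2 scale with the mean of its probe sets), Tgm3 (5.33-fold) and Mctp1 (at least 2.32-fold) were lower. Klrb1f was at least 1.34-fold lower, from 110 to 20.6, and stays uncertain because Klrb1 genes are similar enough to share probe sequence. Ccr2, a chemokine receptor, fell from 1754 to 310 (-2.50 ± 0.27, adjusted p = 0.00266, and 0.0521 without stage 1 NKT array 2). Lmo4, a LIM-domain regulator of transcription, fell 5.38-fold (adjusted p = 0.00435, and 0.0765 and 0.0685 without stage 1 NKT array 1 and array 2).

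Genes of T helper programmes moved in both directions. Among 11 type 2 genes tested, 2 rose and 2 fell (2 and 6 adjusted over the list alone). Il4ra, the receptor of interleukin 4, rose from 219 to 787 (1.85 ± 0.21, adjusted p = 0.00295, and 1.21 with the mean of its probe sets), and the transcription factor gene Nfil3 rose at least 1.88-fold (adjusted p = 0.00354, and 0.0685 without stage 1 NKT array 2). The cytokine gene Il4 fell from 526 to 231 (-1.19 ± 0.17, 2.28-fold) and Il13 fell 2.54-fold (-1.35 ± 0.22, adjusted p = 0.0204). Neither fall passed without stage 1 NKT array 1 (0.131 for Il4, 0.113 for Il13) or array 2 (0.0777 and 0.279), and that of Il13 was also lost without Luxoid array 1 (0.0525) or array 3 (0.0802). As a set the list was not called by camera (median -0.51, adjusted p = 0.131), except with the stricter intensity filter (median -0.85, 0.0164). Of 13 Th1 and NK effector genes 2 rose and 2 fell (2 and 4 adjusted over the list alone), with a median of 0.13 above 0 against a mean of -0.06 and a set test directed downwards (adjusted p = 0.814). With the stricter intensity filter it was directed upwards and called (median 0.32, adjusted p = 0.0496). Gzmb, which encodes granzyme B, was 2.43-fold higher (adjusted p = 0.0358, and 0.0564 to 0.352 when any 1 of the 7 arrays was left out).

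Among 6 type 17 genes 1 fell (2 adjusted over the list alone): Rora, a nuclear receptor, went from 1809 to 428 (-2.08 ± 0.23, adjusted p = 0.00293, and 0.0638 without stage 1 NKT array 2). The type 17 list was directed downwards (median -0.38, adjusted p = 0.0333, and 0.0684 with the replicate number as a block; adjusted p = 0.305 with an estimated correlation). It was not called without stage 1 NKT array 2 (0.177) or Luxoid array 1 (0.152), without the intensity filter (0.167, with the median at 0.00499) or with the stricter one (0.0739). Of 24 cytokine receptor genes 6 rose and 2 fell (7 and 7 adjusted over the list alone), led by Il10ra, Il4ra and Ifngr1, a chain of the interferon gamma receptor (1.69 ± 0.16, 3.23-fold). That list's median was -0.05 with a mean of 0.14, and it was not called (adjusted p = 0.283), except with the stricter filter (0.0164) or the mean of probe sets (0.0485). Of 20 homing and adhesion genes 2 fell and none rose (7 and 3 adjusted over the list alone), and the list was not called either (median -0.17, adjusted p = 0.185). The genes that fell were Ccr2, with adjusted p = 0.0521 without stage 1 NKT array 2, and Cxcr3, a chemokine receptor under the intensity filter in both groups on average (77.7 and 35.5, adjusted p = 0.0208, 0.0635 with the block, and 0.0553 to 0.279 without either stage 1 NKT array, Luxoid array 3 or either CD4SP array).

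Cd69, an early activation marker, rose from 280 to 1162 (2.05 ± 0.18, adjusted p = 0.000955), and Icos, a costimulatory receptor, fell from 6222 to 2877 (-1.11 ± 0.15, adjusted p = 0.00946, and 0.125 and 0.0807 without stage 1 NKT array 1 and array 2). They were the members that passed among 22 genes of T cell receptor signalling and activation (6 higher and 3 lower adjusted over the list alone). That list was directed upwards (median 0.17, adjusted p = 0.00891; adjusted p = 0.305 with an estimated correlation). It was not called without Luxoid array 1 (0.0633). Of 31 transcription factor genes 2 rose and 1 fell (8 and 4 adjusted over the list alone). Bcl6, a transcriptional repressor, rose 2.75-fold (1.46 ± 0.14, adjusted p = 0.00143). The transcription factor list was directed upwards (median 0.12, adjusted p = 0.0174; adjusted p = 0.253 with an estimated correlation). It was not called without stage 1 NKT array 2 (0.0672) or with the mean of each gene's probe sets (0.0509).

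In the list of naive T cell and recirculation genes, 0 of 14 members passed limma's adjusted threshold (2 higher and 2 lower adjusted over the list alone), while the list was directed upwards (median 0.30, adjusted p = 0.0174; adjusted p = 0.305 with an estimated correlation). The list was not called without stage 1 NKT array 1 (0.192) or Luxoid array 2 (0.0531). Bach2, a repressor of effector differentiation, stood at 637 in stage 1 NKT, 1218 in Luxoid NKT and 4176 in CD4SP, with a Luxoid difference of 0.93 ± 0.20 (adjusted p = 0.0760, and 0.0248 with the replicate number as a block). It also passed with the trend model (0.0448). Differences of S1pr1 (0.73 ± 0.17, adjusted p = 0.0918, and 0.0473 with the trend model) and Klf2 (0.52 ± 0.18, 0.294) did not pass. Id2 (-0.74 ± 0.15, 0.0647) passed with the trend model (0.0323) and the mean of probe sets (-0.94, 0.00600). Egr2 (0.82 ± 0.17, 0.0617) passed with the trend model (0.0208), the mean of probe sets (0.0254) and without Luxoid array 1 (0.0412). With a covariate for Y-linked expression, chosen after the data were seen, Bach2 (0.0373), S1pr1 (0.0392) and Egr2 (0.0396) passed. Those of Gata3 (-0.39 ± 0.17), Tbx21 (-0.48 ± 0.16), Myc (-0.28 ± 0.18), Id3 (0.05 ± 0.15), Il17rb (-0.51 ± 0.19), Cd4 (0.12 ± 0.14) and Cd44 (-0.22 ± 0.24) did not either.

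Ribosome biogenesis genes were directed downwards as a list (median -0.28, adjusted p = 0.0130; adjusted p = 0.253 with an estimated correlation) with 0 of 20 members past limma's adjusted threshold and 0 adjusted over the list alone. That call was lost without stage 1 NKT array 2 (0.0672) or Luxoid array 1 (0.0633). Interferon-stimulated genes were also directed downwards (median -0.16, adjusted p = 0.0333, and 0.367 with the block; adjusted p = 0.540 with an estimated correlation). They were not called without stage 1 NKT array 2 (0.177) or Luxoid array 3 (0.312). Of their 16 members 1 fell (1 adjusted over the list alone), Oasl2, an interferon-induced gene, by 0.78 on the log2 scale (adjusted p = 0.0278, 0.0530 with the block, and 0.0585 to 0.320 when any array other than Luxoid array 2 was left out). No member of the cell cycle list (31 genes, median 0.10, adjusted p = 0.0575), the SLAM and SAP list (8 genes, median -0.03, 0.814), the glycolysis list (12 genes, median -0.01, 0.813), the cholesterol synthesis list (12 genes, median -0.000819, 0.641) or the survival and apoptosis list (13 genes, median -0.03, 0.737) passed. The cell cycle list was called with the stricter filter (0.0410), array weights (0.0236), the mean of probe sets (0.0485), without Luxoid array 2 (0.00203) and with the Y-linked covariate (0.0288). Otherwise these lists were not called, and the medians of the last 4 were below 0 with set tests directed upwards.

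Markers of other cells were read beside these groups. CD8 lineage genes were directed upwards (median 0.35, adjusted p = 0.00228; adjusted p = 0.253 with an estimated correlation), with 1 of 5 members past the threshold (2 adjusted over the list alone). This member, Cd8a, was at 87.8 in stage 1 NKT, 159 in Luxoid NKT and 141 in CD4SP (0.86 ± 0.16, adjusted p = 0.0342, 0.0518 with all probe sets tested, and 0.0659 to 0.283 when any array other than Luxoid array 1 was left out). Immature double-positive thymocyte genes were directed upwards (median 0.41, adjusted p = 0.00891, and 0.0770 without stage 1 NKT array 2; adjusted p = 0.305 with an estimated correlation), with Cd8a the 1 of 7 members called (1 adjusted over the list alone). Fcer1g, a signalling adaptor of NK and myeloid cells, rose from 235 to 924 (1.98 ± 0.15, adjusted p = 0.000554) and was the 1 of 4 NK cell markers called (1 adjusted over the list alone). The NK list had a median of 0.34 (adjusted p = 0.0470, and 0.115 with the block; adjusted p = 0.305 with an estimated correlation) and lost its call without stage 1 NKT array 2, Luxoid array 1 or 3, or either CD4SP array (0.0539 to 0.316). Its median turned to -0.15 without stage 1 NKT array 2. It was also not called without the intensity filter (median 0.08, 0.472), after another quantile normalization (0.0507) or after median centring (0.0533). Of 9 regulatory T cell markers 1 fell (3 lower and 2 higher adjusted over the list alone): Nrp1, a semaphorin co-receptor, by 1.74 on the log2 scale (adjusted p = 0.00238). The regulatory T list was not called (median 0.06, mean -0.21, adjusted p = 0.668).

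Of 3 thymic epithelium markers none passed limma's adjusted threshold (1 higher adjusted over the list alone), and the list was directed upwards (median 0.53, adjusted p = 0.0369; adjusted p = 0.305 with an estimated correlation). It was not called without stage 1 NKT array 1 (0.192) or 2 (0.0532) or Luxoid array 1 (0.0514) or 2 (0.0631), nor without the intensity filter (0.168). B cell (4 genes, median 0.02, mean -0.18, adjusted p = 0.668), myeloid (5, -0.11, 0.389), gamma delta T (4, -0.48, 0.378), handling stress (6, 0.19, 0.0747, but 0.0470 with the trend model and 0.0188 without stage 1 NKT array 2) and sex-linked markers (4, 0.56, 0.813) had no member past the threshold and were not called (adjusted over the list alone, 1 B cell gene was lower and 1 gamma delta T gene was higher and 2 lower). Of 8 erythroid genes, 0 passed the intensity filter, so that list was not tested.

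In all, 169 of 10874 genes differed between Luxoid and stage 1 NKT at an adjusted p under 0.05, 98 higher and 71 lower in Luxoid, of which 129 differed at least 2-fold. With the replicate number as a block 170 were called, 133 of them in both fits. The count of 169 became 103 without Luxoid array 3. It was lower still without either stage 1 NKT array, or without both mixed-sex pools, an alternative chosen after the data were seen. Each of these latter fits left 1 stage 1 NKT array, so the fall does not tell sex from the loss of arrays. Among 25 lists camera called 10 with its preset correlation (4 without stage 1 NKT array 2, 5 without Luxoid array 1), and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05.

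**Figure D1:**
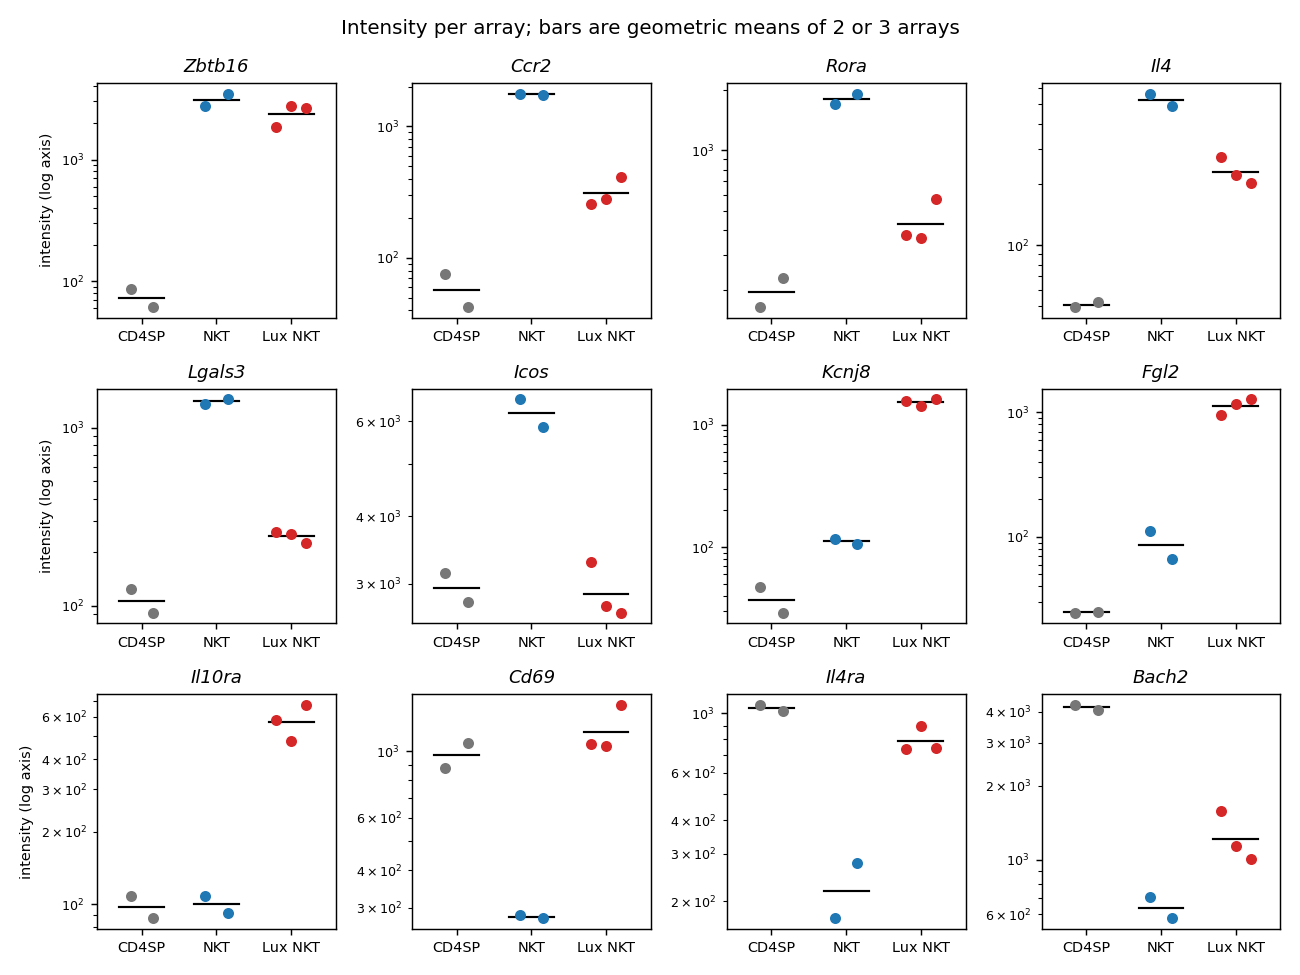
Intensity of 12 genes on each of the 7 arrays (vertical log axis), with CD4SP (grey, 2 arrays), stage 1 NKT (blue, 2 arrays) and Luxoid stage 1 NKT (red, 3 arrays); each point is an array and each bar a geometric mean. Luxoid Ccr2 lies at 310 between 1754 in stage 1 NKT and 56.6 in CD4SP, while Kcnj8 lies at 1529 in Luxoid NKT, above both other groups.

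The comparison of stage 1 NKT with CD4SP thymocytes gave what set these sorted cells apart. Lineage, the transgene and the sort, which took NKT cells low in CD24, differed together. S100a4, a calcium-binding protein, was 52.7-fold higher in stage 1 NKT (5.72 ± 0.25, adjusted p = 8.69e-06) and S100a6 45.8-fold higher (5.52 ± 0.27). The chemokine receptor genes Ccr2 (at least 21.4-fold), Cxcr6 (at least 11.1-fold) and Ccr4 (3.47 ± 0.24) were higher. The integrin gene Itgae was higher by 4.64 ± 0.30 (also over 1.5 times smaller with the mean of its probe sets, and 2.36 without probe sets whose IDs mark shared sequence). Plac8 (4.75 ± 0.20), Niban1 (4.86 ± 0.16), Rbpms (at least 9.94-fold), Moxd1 (at least 7.81-fold) and Gm36723 (at least 19.6-fold) were also higher. The probe sets of the T cell receptor genes Trgv4 (74.7-fold) and Trgv1 (59.2-fold) were brighter in stage 1 NKT and those of Trav12n-1 (9.57-fold) and Trav12n-2 (9.43-fold) dimmer, and they stay uncertain because variable genes share sequence. Cd24a, the surface protein used in the sort, was at 14.1 against 242 (at least 2.96-fold lower), and Cd4 at 2053 against 6272 (-1.61 ± 0.16). Tsc22d3 (-3.70 ± 0.22, and -1.84 with the mean of its probe sets), Tmie (-3.65 ± 0.28, and -2.53 without probe sets of shared sequence), Arhgap20 (at least 4.14-fold) and Tdrp (-2.89 ± 0.20) were lower in stage 1 NKT.

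Several effector genes were higher in stage 1 NKT. Of 11 type 2 genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), with Maf, a transcription factor (3.67 ± 0.34), Il4 (at least 6.41-fold) and Il13 (2.73 ± 0.24) among those higher and Il4ra (-2.26 ± 0.23) lower. With the mean of probe sets Maf was at 2.71 and Il4ra at -1.50. The type 2 list had a median of 1.02 (adjusted p = 0.0120; adjusted p = 0.183 with an estimated correlation). Of 13 Th1 and NK effector genes 7 rose (8 higher and 1 lower adjusted over the list alone; median 0.86, adjusted p = 0.00548; adjusted p = 0.183 with an estimated correlation), among them Nkg7, a cytotoxic granule protein (3.24 ± 0.19), Id2, an inhibitor of DNA binding (3.02 ± 0.17), and Il2rb (1.47 ± 0.20). This list was not called without the intensity filter (0.0570). Of 20 homing and adhesion genes 8 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.47, adjusted p = 0.00422; adjusted p = 0.183 with an estimated correlation). Of 6 type 17 genes 1 rose (1 adjusted over the list alone), Rora (3.21 ± 0.25, and 2.29 with the mean of its probe sets), and the list was not called (median 0.15, adjusted p = 0.518). Of 31 transcription factor genes 11 rose and 4 fell (11 and 5 adjusted over the list alone), without a call for the list (median 0.08, adjusted p = 0.556).

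Most cell cycle genes and some genes of 3 metabolic lists were also higher in stage 1 NKT. Of 31 cell cycle genes 24 rose and none fell (27 and 0 adjusted over the list alone), including Ccnb2, a mitotic cyclin (2.82-fold), and Aurka, a mitotic kinase (1.44 ± 0.15, and 0.62 with the mean of its probe sets). The list had a median of 0.91 (adjusted p = 1.63e-11; adjusted p = 0.183 with an estimated correlation). Of 12 glycolysis genes 6 rose (7 adjusted over the list alone; median 0.57, adjusted p = 0.00384; adjusted p = 0.283 with an estimated correlation), with Tpi1, triosephosphate isomerase, at 1.61 ± 0.25. Of 12 cholesterol synthesis genes 4 rose (4 adjusted over the list alone; median 0.48, adjusted p = 0.0173, and 0.0692 without CD4SP array 2; adjusted p = 0.274 with an estimated correlation), including Idi1 (1.08 ± 0.16) and Cyp51 (0.99 ± 0.16). Of 20 ribosome biogenesis genes 3 rose (3 adjusted over the list alone; median 0.32, adjusted p = 0.0222, and 0.0647 without stage 1 NKT array 2; adjusted p = 0.183 with an estimated correlation). That list was not called with the stricter intensity filter (0.0528).

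The naive T cell genes that passed were lower in stage 1 NKT, while receptor signalling genes went both ways. Of 14 naive T cell and recirculation genes 8 fell and none rose (10 lower and 1 higher adjusted over the list alone; median -0.88, adjusted p = 1.71e-08; adjusted p = 0.183 with an estimated correlation), with Bach2 (-2.71 ± 0.22), Als2cl (-2.40 ± 0.15), Actn1 (-1.86 ± 0.25) and Ccr7, a lymph node homing receptor (-1.14 ± 0.15). Of 22 T cell receptor signalling genes 11 fell and 6 rose (13 and 6 adjusted over the list alone; median -0.64, adjusted p = 0.00222; adjusted p = 0.183 with an estimated correlation). The checkpoint receptor Ctla4 (at least 4.74-fold) and the nuclear receptor Nr4a3 (-2.89 ± 0.37, and -2.26 with the mean of its probe sets) were lower, while Pdcd1, another checkpoint receptor (3.28 ± 0.17), and Spry2, a signalling inhibitor (at least 3.17-fold), were higher. Of 24 cytokine receptor genes 6 fell and 5 rose (10 and 6 adjusted over the list alone; median -0.08, adjusted p = 0.0376; adjusted p = 0.187 with an estimated correlation), with Il6st 4.01-fold lower and Il18r1 at 2.15 ± 0.29. This call was lost without stage 1 NKT array 1 (0.0532), without CD4SP array 2 (0.0749), after another quantile normalization (0.0683) and without the intensity filter (0.0912).

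Of 13 survival genes 4 fell and 2 rose (5 and 2 adjusted over the list alone; median -0.35, adjusted p = 0.0120; adjusted p = 0.187 with an estimated correlation), with the pro-apoptotic Bcl2l11 at -1.88 ± 0.24. Of 16 interferon-stimulated genes 1 rose, Oas1a (1.56 ± 0.26), and 1 fell (1 and 1 adjusted over the list alone; median -0.25, adjusted p = 0.0303; adjusted p = 0.489 with an estimated correlation). The interferon list was not called without stage 1 NKT array 1 (0.0845), without CD4SP array 1 (0.0674) or without the intensity filter (0.0912). Of 8 SLAM and SAP genes 2 rose and 1 fell (2 and 2 adjusted over the list alone), the latter being Slamf1 (-2.12 ± 0.20); that list's median was 0.24, its mean -0.02 and its test directed downwards (adjusted p = 0.957).

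Among markers of other cells, all 4 gamma delta T genes tested were higher in stage 1 NKT (4 adjusted over the list alone; median 2.50, adjusted p = 0.000160; adjusted p = 0.183 with an estimated correlation), among them Cd163l1 (2.45 ± 0.21) and Sox13 (at least 3.21-fold). Of 7 immature thymocyte genes 4 fell (4 adjusted over the list alone; median -0.68, adjusted p = 0.000401; adjusted p = 0.183 with an estimated correlation), including Dntt, terminal transferase (at least 6.01-fold, and -1.33 on the log2 scale without probe sets of shared sequence). Of 9 regulatory T cell markers 5 fell and 2 rose (6 and 3 adjusted over the list alone; median -0.72, adjusted p = 0.00548; adjusted p = 0.183 with an estimated correlation). Gpr83 was at -2.48 ± 0.23, and Capg, which went the other way, at 2.41 ± 0.27 (1.68 with the mean of its probe sets). Of 3 thymic epithelium markers 1 fell (1 adjusted over the list alone; median -0.62, adjusted p = 0.0442, and 0.108 without stage 1 NKT array 1 and 0.144 without CD4SP array 2; adjusted p = 0.265 with an estimated correlation). This call was also lost without the filter (0.0570), with the trend model (0.0533) and after another quantile normalization (0.0683). CD8 lineage markers (2 higher and 3 lower of 5, the same counts adjusted over the list alone) had a median of -0.68 and a mean of 0.07 and were not called (adjusted p = 0.556). B cell (median -0.23, mean 0.10, adjusted p = 0.556), myeloid (-0.48, 0.149, but 0.0101 without the filter and 0.0479 without CD4SP array 1), NK cell (0.36, 0.898), handling stress (-0.39, 0.0859, but 0.0248 without stage 1 NKT array 2) and sex-linked markers (-0.07, mean 0.58, 0.898) were not called.

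In total 1621 genes differed between stage 1 NKT and CD4SP, 1177 higher and 444 lower in stage 1 NKT, and 2616 with the replicate number as a block (1844 and 772), of which 1618 were called in both fits. Of the 1621 genes, 774 differed at least 2-fold, and the count was 643 and 749 without stage 1 NKT arrays 1 and 2, 856 and 714 without CD4SP arrays 1 and 2, and 520 without both mixed-sex pools.

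The comparison of Luxoid NKT with CD4SP showed what of that difference was present in the mutant. Moxd1 was at least 22.5-fold higher in Luxoid NKT (adjusted p = 1.89e-06), and Fgl2 (at least 13.8-fold), Kcnj8 (at least 18.6-fold), Rbpms (at least 13.1-fold), S100a4 (43.2-fold) and S100a6 (28.3-fold) were also higher. Cxcr6 (at least 6.16-fold), Itgae (3.36 ± 0.27), Pdcd1 (3.34 ± 0.15), Nkg7 (3.53 ± 0.17), Fcer1g (3.61 ± 0.15), Maf (2.73 ± 0.31), Ccr2 (at least 3.78-fold), Id2 (2.28 ± 0.15) and Il4 (at least 2.82-fold) were higher, each at an adjusted p of 0.000551 or less. Another probe set of Maf pointed the other way. With the mean of probe sets Maf was at 1.54 and Itgae at 2.35, and without probe sets of shared sequence Itgae was at 1.34. Rora was 2.19-fold higher (adjusted p = 0.0113, and 0.104 without CD4SP array 1). Tmie (-3.84 ± 0.26, and -2.42 without probe sets of shared sequence), Arhgap20 (at least 4.14-fold), F13a1 (at least 2.32-fold), Als2cl (-2.82 ± 0.14) and Ctla4 (at least 4.74-fold) were lower. Icos, at 2877 against 2951, did not differ beyond the threshold (-0.04 ± 0.15, adjusted p = 0.905).

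Of 31 cell cycle genes 26 rose in Luxoid NKT relative to CD4SP (27 adjusted over the list alone; median 1.08, adjusted p = 1.73e-14; adjusted p = 0.229 with an estimated correlation), with Aurka at 1.55 ± 0.14 (0.79 with the mean of its probe sets). Of 11 type 2 genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 1.39, adjusted p = 0.00220; adjusted p = 0.229 with an estimated correlation). Of 20 homing genes 9 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.50, adjusted p = 0.00307; adjusted p = 0.230 with an estimated correlation). Of 12 glycolysis genes 6 rose (6 adjusted over the list alone; median 0.51, adjusted p = 0.000978; adjusted p = 0.319 with an estimated correlation), and of 12 cholesterol synthesis genes 5 rose (5 adjusted over the list alone; median 0.33, adjusted p = 0.0108; adjusted p = 0.319 with an estimated correlation). Of 14 naive T cell genes 7 fell (8 lower and 2 higher adjusted over the list alone; median -0.61, adjusted p = 0.000177; adjusted p = 0.229 with an estimated correlation), with Bach2 at -1.78 ± 0.20. Of 16 interferon-stimulated genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.38, adjusted p = 0.000614; adjusted p = 0.319 with an estimated correlation). Of 13 survival genes 4 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.33, adjusted p = 0.0205, and 0.0692 without the filter; adjusted p = 0.270 with an estimated correlation).

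Of 9 regulatory T cell markers 7 were lower and 2 higher in Luxoid NKT than in CD4SP (the same counts adjusted over the list alone; median -1.42, adjusted p = 0.000614; adjusted p = 0.229 with an estimated correlation), with Ikzf4 at -2.29 ± 0.22. All 4 gamma delta T genes were higher (4 adjusted over the list alone; median 2.59, adjusted p = 0.000467; adjusted p = 0.229 with an estimated correlation), with Cd163l1 at 2.44 ± 0.19 and Sox13 at least 1.14-fold higher (adjusted p = 0.0448, 0.111 with the block, 0.0638 without the filter, 0.0532 with all probe sets tested, and 0.106 to 0.246 without Luxoid array 1 or 3 or either CD4SP array). Of 4 lists the call was less stable. Th1 and NK effector genes (6 higher and 1 lower of 13; 8 and 4 adjusted over the list alone) had a median of 1.06 (adjusted p = 0.0399, and 0.0916 with the block; adjusted p = 0.319 with an estimated correlation). They were not called without Luxoid array 1 (0.0523) or CD4SP array 1 (0.0627), after median centring (0.0538), or without the filter (0.385), where the median was -0.11. Transcription factor genes (13 higher and 5 lower of 31; 14 and 6 adjusted over the list alone) had a median of 0.25 (adjusted p = 0.0436, and 0.0916 with the block; adjusted p = 0.230 with an estimated correlation). They were not called without either stage 1 NKT array (0.0510), Luxoid array 3 (0.0713) or CD4SP array 2 (0.0535). The call was also lost with the stricter filter (0.238), without probe sets whose IDs mark shared sequence (0.0665), after median centring (0.0541) and with the trend model (0.0512).

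Myeloid markers (1 lower of 5; 3 adjusted over the list alone) had a median of -0.58 (adjusted p = 0.0436, and 0.0916 with the block; adjusted p = 0.261 with an estimated correlation). They were not called without either stage 1 NKT array (0.0510), Luxoid array 1 (0.0523) or 3 (0.0713), or CD4SP array 2 (0.120). The call was also lost after another quantile normalization (0.163) or median centring (0.101), with the mean of probe sets (0.172), without probe sets whose IDs mark shared sequence (0.155) and with the trend model (0.0516). Immature thymocyte markers (3 lower of 7; 3 adjusted over the list alone) had a median of -0.20 (adjusted p = 0.0436; adjusted p = 0.324 with an estimated correlation). They were not called without either stage 1 NKT array (0.0642), Luxoid array 1 (0.0523) or CD4SP array 2 (0.0729), nor without the filter (median -0.05, 0.424). The T cell receptor signalling list (median -0.42, adjusted p = 0.0589, and 0.0386 after median centring), the type 17 list (-0.05, mean 0.02, 0.671), cytokine receptors (-0.12, mean 0.05, 0.595) and ribosome biogenesis (0.09, 0.597) were not called. SLAM and SAP (0.13, mean -0.04, 0.989), CD8 lineage (0.17, 0.510), NK cell (0.40, 0.597), B cell (-0.38, 0.510), thymic epithelium (-0.12, 0.595), handling stress (-0.07, mean 0.26, 0.597) and sex-linked markers (0.50, 0.989) were not called either.

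In total 1831 genes differed between Luxoid NKT and CD4SP, 1232 higher and 599 lower in Luxoid NKT, and 809 of them at least 2-fold. The count was 978 and 866 without CD4SP arrays 1 and 2 and 918 without both mixed-sex pools.

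Of the 169 genes that differed between the NKT groups, 105 also differed between stage 1 NKT and CD4SP, and 77 of the 105 had opposite signs in the 2 comparisons. Opposite signs mean by definition that Luxoid NKT moved toward the CD4SP level. Only a move past that level by more than the original gap could end farther from it. In Luxoid NKT 73 of the 77 lay nearer to the CD4SP level and 4 lay farther from it, on its other side: Sema4f, Sgk1, Gsto1 and Nrp1 (Sgk1 and Gsto1 are named after their values were seen). In all, 34 of the 77 lay on the other side of the CD4SP level by the sign of the difference alone, some of them by little, such as Icos (-0.04). Lists of these sizes drawn independently would share 7.69 genes that are lower in Luxoid and higher in stage 1 NKT than CD4SP, against 45 observed, and 4.00 of the opposite kind, against 32 observed. Ccr2, Rora, Il4, Il13 and Lgals3 were of the first kind and Il4ra, Cd69, Tsc22d3 and Bcl6 of the second. With the same sign 28 genes were called in both comparisons, 24 of them higher in Luxoid NKT (10.6 for independent lists), including Fgl2, Kcnj8 and Moxd1, and 4 lower (2.90). Of the 64 genes called between the NKT groups alone, 58 differed between Luxoid NKT and CD4SP, Il10ra among them. Of the 77 genes, 48 were not called between Luxoid NKT and CD4SP. The 77 genes made up 4.75% of the 1621 genes that set stage 1 NKT apart from CD4SP.

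Both comparisons contain the 2 stage 1 NKT arrays, so their errors are linked. The covariance of the differences over all genes was -0.0540, against a mean of -0.0236 (range -0.0292 to -0.0209) in 100 simulated sets with no difference between groups, and the correlation was -0.26 against -0.55. In 100 simulated sets that kept the differences of stage 1 NKT from CD4SP and gave Luxoid NKT no difference from stage 1 NKT, the mean was -0.0232 (range -0.0339 to -0.0174). Those sets held at most 4 genes called in opposite directions, since few genes were called between the NKT groups in them. The 2 arrays cannot be split, so part of the excess may come from sharing them. The count of 77 was 28 and 26 without stage 1 NKT arrays 1 and 2, 47 and 44 without CD4SP arrays 1 and 2, 50 at a 2-fold threshold and 6 without both mixed-sex pools. Over the 1621 genes the slope of Luxoid minus CD4SP on stage 1 NKT minus CD4SP was 0.865, against 0.956 (0.927 to 0.965) in simulated sets in which the mutation had no effect.

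**Figure D2:**
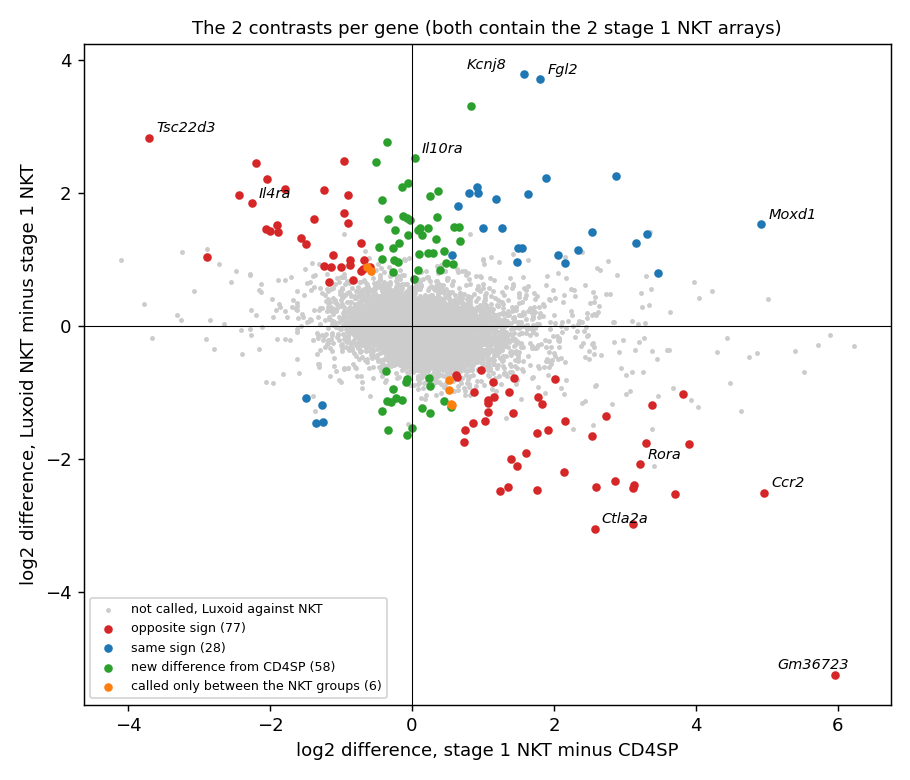
Each point is 1 of 10874 genes, with the log2 difference stage 1 NKT minus CD4SP on the horizontal axis and Luxoid minus stage 1 NKT on the vertical axis. Colours mark the 169 genes called between the NKT groups: 77 with opposite signs (red), 28 with the same sign (blue), 58 called against CD4SP in Luxoid NKT only (green) and 6 called only between the NKT groups (orange).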

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

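The test of genes within 10 Mb of Zbtb16 was planned before its result was seen; the windows of 5 and 20 Mb and the tests of sex, shared arrays and CD4SP-like cells were chosen only after the results were seen. Probe sets that the annotation gives no gene or several genes were outside the gene comparisons, and 6 of 3751 differed between Luxoid and stage 1 NKT by limma, 5 higher and 1 lower in Luxoid (0.160%). Their log2 differences were 2.01, 2.08, 2.14, 2.21 and 1.34 for those higher (the last against stage 1 NKT arrays under the intensity filter) and -1.69 for that lower, and their genes are not named here.

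Genes near Zbtb16 form the first pattern. Within 10 Mb, 4 of 138 genes (2.90%) were called between the NKT groups, against 1.54% elsewhere (Fisher's exact test, one-sided p = 0.169), and the p was 0.0349 within 5 Mb and 0.302 within 20 Mb. The 4 genes, Exph5 (at least 1.73-fold), Il10ra (2.52 on the log2 scale), Poglut3 (0.79) and Scn4b (at least 1.98-fold), were higher in Luxoid NKT; Exph5, Poglut3 and Scn4b are named after their values were seen. DNA of another strain carried along with the Luxoid allele could account for such genes, and it stays open, as does an effect of PLZF on them, because few genes lie in the window.

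The second pattern is that arrays with the same number deviate together. Genes of X and Y alone are argued against, because the lowest correlation of same-numbered pairs over autosomal genes was 0.261. Sex of the pooled mice acting on autosomal genes stays open. Luxoid array 3, with both Xist and Y-linked signal, lay at 0.592 between array 1 at 0 and array 2 at 1. The 95% bootstrap interval of this position, 0.551 to 0.633, resamples genes and does not measure the spread between arrays. An array that did not share the deviation could also lie between arrays 1 and 2, so the position cannot decide on sex. Over autosomal genes, deviations of Luxoid array 3 correlated at r = 0.0788 with stage 1 NKT array 2 and r = 0.00878 with CD4SP array 2. Sex and number cannot be told apart here, since every array numbered 1 lacked Y-linked signal, and a shared day of work may also contribute but was not tested.

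The third pattern is the 77 genes called in opposite directions in the 2 comparisons that share stage 1 NKT. The 2 shared NKT arrays stay open as a cause. The covariance was -0.0540, beyond the range of -0.0339 to -0.0174 in simulated sets that kept the differences from CD4SP. That range may be too narrow where many genes deviate together, as they do in same-numbered arrays, and this was not tested. CD4SP-like cells in the Luxoid sort are argued against as the whole cause for genes chosen on arrays of 1 number (101 or 75 genes). In these, stage 1 NKT and CD4SP were at least 2-fold apart and Luxoid at least 2-fold from stage 1 NKT toward CD4SP. This set is not that of the 77 genes. On arrays of the other number its genes needed a median CD4SP share of 73.8% (64.2 to 80.6) or 82.6% (70.4 to 88.1). The other genes at least 2-fold apart needed 5.27% (1.92 to 8.67) or 6.04% (1.58 to 9.89). These 95% bootstrap intervals resample genes on 1 array per group and do not measure the spread between arrays. A small share of CD4SP-like cells stays open, although the sort for CD1d tetramer and low CD24 selects against them. Dependence of these genes on PLZF is the biological explanation that the design names, and it may act together with either.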

How the results depend on the processing

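The covariate for Y-linked expression and the removal of both mixed-sex pools were chosen only after the results were seen. Removing both pools left stage 1 NKT with array 1 alone. Without both mixed-sex pools, 10 genes differed between Luxoid and stage 1 NKT, 520 between stage 1 NKT and CD4SP and 918 between Luxoid NKT and CD4SP, and 6 genes had opposite signs in the 2 comparisons; fewer arrays were fitted. Leaving out 1 array at a time gave 55 to 178 (169 with all arrays), 643 to 1846 (1621), 866 to 1726 (1831), and 26 to 80 for the genes with opposite signs (77). The counts that moved over 1.5 times were those without stage 1 NKT array 1 (64, 643 and 28) or 2 (55, 749 and 26), Luxoid array 3 (103), CD4SP array 1 (856, 978 and 47) or 2 (714, 866 and 44). A 2-fold threshold left 774, 809 and 50 by its construction, and testing every probe set gave 2876 for Luxoid NKT against CD4SP because more were tested. The replicate block gave 2616 for stage 1 NKT against CD4SP, the cause was not tested; of the 169 and 1831 genes, 133 and 1738 were called with it. It changed no call of a named gene or list beyond those given in the report, Gcsam (0.0533, and 0.0510 without Luxoid array 3) and Il2rb (0.0606, and 0.0638 to 0.284 when any 1 array was left out) in Luxoid against stage 1 NKT. With the covariate 7, 16 and 10 lists were called in the 3 contrasts (10, 16 and 14 without it). It ended 4 calls of Luxoid NKT against CD4SP: Th1 and NK effector (0.0801, median 1.07), transcription factor (0.0712, 0.24), myeloid (0.0620, -0.61) and immature thymocyte (0.0822, -0.20). Between the NKT groups it ended those of type 17, interferon-stimulated, NK cell and thymic epithelium genes (0.0570 each, medians -0.39, -0.15, 0.40 and 0.51). These 8 medians stayed close to those without the covariate, so the lost calls do not show that sex accounts for the shifts. Of lists, 4 to 9 were called between the NKT groups when 1 array was left out (10 with all; 4 without stage 1 NKT array 2, 5 without Luxoid array 1), and with an estimated correlation limma's camera called 0 in each contrast (3, 3 and 5 at an unadjusted p under 0.05). The set test of the Th1 and NK effector list turned from downwards to upwards (adjusted p = 0.0496) with the stricter filter, while its median was above 0 in both (0.13 and 0.32); the cause was not tested. Of 41, 91 and 90 named genes called in the 3 contrasts, 24, 61 and 70 were called whichever array was left out, and 35, 83 and 80 under every other alternative fixed in the design. A named gene that an alternative's filter or probe set rule removed was not tested there, and the 35, 83 and 80 do not count it as lost. Probe sets near the background limit small differences.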

Other observations

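No test in this part was chosen to explain a value. Jun, an immediate early gene, read 111 and 735 in the stage 1 NKT arrays, 62.7, 561 and 479 in the Luxoid arrays, and 59.0 and 88.1 in the CD4SP arrays. Fos read 22.2 and 136 in stage 1 NKT, 108, 140 and 112 in Luxoid NKT, and 88.8 and 84.5 in CD4SP.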
